A study of Rattus norvegicus with 93 samples.

How the data were processed

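Polyadenylated RNA of the rostromedial tegmental nucleus (RMTg) of outbred rats was sequenced, with 1 library per animal. The labels name 93 samples in 1 group and give no treatment, behaviour, sex or genotype. One sample that the labels mark as removed for want of a genotype has no column and was not used here, which leaves 92 libraries. Labels of 2 libraries note an identifier that was corrected after a genotype mismatch; both were kept. Sample identifiers fall into number series, and a gap of over 50000 between neighbouring identifiers was taken to start a new series (A to F). What a series stands for is not stated, so series were used only to look for batches.

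The deposited table holds log2 values for 38354 genes, and the submitters' processing notes name kallisto 0.48. From the values, each entry is log2 of an estimated read count plus 1: of the back-transformed values above 0 and under 20, 49.98% were whole numbers within 0.01. Back-transformed totals differed between libraries from 1.72 to 50.2 M (M, 1000000 counts), so the authors had removed neither depth nor transcript length. The genome build is not stated. Positions are printed as the table gives them; those of all 38278 genes whose symbol is in the RefSeq gene table used here equal an end of that gene there. Because the values are not adjusted for transcript length, levels of different genes within a library were not compared, and a planned test of fixed gene pairs was left out for that reason. All 9 mitochondrially encoded genes of a fixed list and Ccdc153 were not used here, because the table has no row under those symbols.

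Values were back-transformed, scaled to counts per 1000000 (CPM) with each library's total and taken as log2 of CPM plus 1. Genes with a log2 value of at least 1 in at least 20% of libraries were kept, which left 18948 genes over all 92 libraries. The tests, the 32 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Libraries were then seen to fall into 3 kinds by the features that took most counts. Kind 3 was defined by Nif3l1 taking over 20% of the counts, and kind 2 by LOC120093067 and Zfp532 taking over 10% together. All other libraries are kind 1. The kinds are a description of the libraries, and no p-value was computed between them. Explanations for the kinds were weighed only by limits set on differences between them. Every planned result was computed over all 92 libraries and again within the 49 libraries of kind 1 (18749 genes). That restriction, the comparisons of pairs of series, 3 further lists (long neuronal genes, respiratory chain genes and ribosomal RNA features) and the alternatives run within the 49 libraries were chosen after seeing the data.

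A list's score in a library was the mean z-scored log2 value of its members past the filter, for lists with at least 3 of them. Scores were correlated with Pearson's r and Spearman's rho, with two-sided permutation tests (100000 permutations for the 49 libraries) and Benjamini-Hochberg adjustment over all pairs of lists. Each r was computed again without the 2 libraries farthest from the median of the x-axis score and within each series of at least 6 libraries. Genes were tested for a slope on each of 5 scores with limma 3.58.1 in R 4.3.3 (moderated statistics with a mean trend), at a Benjamini-Hochberg adjusted p under 0.05, leaving the list's own members out of the count, and 100 draws with permuted scores gave the chance level. Series were compared with limma's F test and pairs of series with limma's moderated test. For each, 100 splits of the same libraries into groups of the same sizes were compared, the real split included. For a fixed list, counts are given over all genes tested and adjusted over the list alone.

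The spread of a list was the median of its members' SD over libraries after removing the trend of SD on mean expression. It was placed among 10000 random lists of the same size matched on expression decile. A gene was said to have 2 separated levels when sorted values had a gap of at least 1 log2 unit with at least 5 libraries on each side; 20 sets of normal draws with each gene's mean and SD gave the number expected. The median correlation of adjacent genes, after removing 10 principal components, was set against 1000 shuffles of gene order.

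The text names members of the fixed lists and, by a rule set in advance, the 15 genes with the largest positive and the 6 with the most negative slope on each score that passed the threshold with 1 sign in every series of at least 6 libraries, the 12 genes of largest residual SD, the 10 genes with the widest gap and any on Y, the 6 neighbouring pairs of highest r and the 10 genes of smallest p between series. One gene that the rule picks was not used here. Symbols starting LOC, RGD, AABR or ENSRNOG or ending in Rik were passed over. Other genes are named where stated, chosen after their values were seen.

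The slope, series and gap procedures were tested on simulated data made from the 49 libraries. Slopes of 0.25, 0.5 and 1 log2 unit per SD of a score were recovered for 91.04%, 95.52% and 100% of the genes changed. Series shifts of 0.5, 1 and 2 log2 units were recovered for 64.18%, 98.51% and 100%, and separations of 2 and 4 log2 units for 46% and 99%. Of 17749 unchanged genes, 9, 12 and 1 were called in the 3 procedures. Changes were planted only in genes with mean CPM above those of some named genes, such as Ntf3 (1.37), Nmur2 (1.59) and Otx2 (1.15). Recovery at such low levels was not simulated. Unchanged genes were drawn independently and the score was known without error. These rates therefore do not carry over to real data, in which genes are correlated.

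Alternatives covered no low-value filter (a gene above 0 in at least 2 libraries), a filter at 80% of libraries, a pseudocount of 0.1, quantile normalization, median-of-ratios scaling, leaving out the relabelled libraries, the 5 libraries least correlated with the others or the 2 farthest from the median score, series, oligodendrocyte score, log10 total or Xist and Ddx3y as covariates, the first principal component as score, rank tests, limma-voom weights, totals with or without the dominant features, an interpeduncular score of the members that did not pass, other gap settings, and no principal components removed or only pairs over 10 kb apart for neighbours. Series as a covariate meant centring values and scores within each series, with slopes per SD of the centred score. No series terms were fitted, which makes the p-values of those slopes somewhat too small. Depth limits the precision of low CPM values most in libraries of kinds 2 and 3. Reads without molecular identifiers are not independent molecules, so counting error understates the uncertainty of a value within a library; errors given are SD between libraries or SE of a fit. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.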

Results

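Expression in the RMTg, an inhibitory nucleus of the brainstem that projects to midbrain dopamine neurons, was measured in 92 libraries from outbred rats, collected for genetic analyses of avoidance learning in addiction. All libraries belong to 1 group. Identifier series A to F held 6, 34, 25, 13, 7 and 7 libraries. Estimated counts per library ranged from 1.72 to 50.2 M (M, 1000000 counts), with a median of 12.1 M, and the number of genes above 0 ranged from 3004 to 28273. No pair of libraries was a duplicate of another: the lowest chi-square per gene over 4186 pairs was 4.10, and 0 pairs were identical.

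The libraries fell into 3 kinds by the features that took most of their counts. In the 49 libraries of kind 1, LOC120093067 and Zfp532 together took 1.41% to 5.50% of the counts (median 2.78%), and 23690 to 28273 genes were above 0. In the 32 libraries of kind 2 the same pair took 19.8% to 56.02% (median 41.7%). In the 11 libraries of kind 3, Nif3l1 took 28.8% to 51.9% (median 39.5%), and only 3004 to 14284 genes were above 0. Totals were 9.55 to 50.2 M in kind 1, 2.29 to 13.7 M in kind 2 and 1.72 to 8.43 M in kind 3. Series A held 5 libraries of kind 2 and 1 of kind 3, and series D held 12 of kind 1 and 1 of kind 2. Series B held 7, 18 and 9 libraries of kinds 1, 2 and 3, and series C held 16, 8 and 1. The 7 libraries of series E and the 7 of series F were all of kind 1. The first principal component held 80.2% of the variance over all 92 libraries and 16.97% within kind 1.

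**Figure D1:**
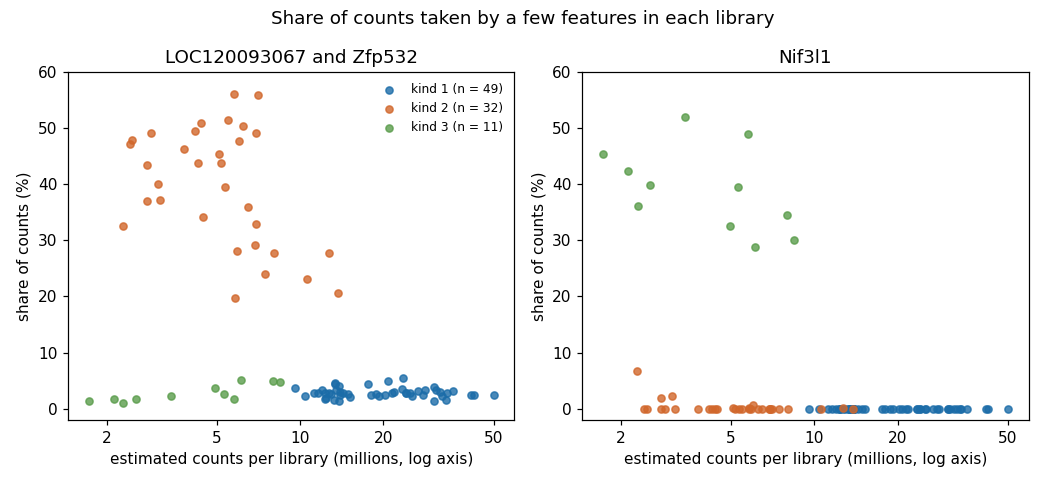
Share of counts taken by LOC120093067 and Zfp532 together (left) and by Nif3l1 (right) against estimated counts per library, on a log axis, with 1 point per library coloured by kind. Kind 2 libraries sit between 19.8% and 56.02% on the left and kind 3 libraries between 28.8% and 51.9% on the right.

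With the dominant features left out of the totals, respiratory chain and ribosomal protein genes were lower in kind 2 than in kind 1 while long neuronal genes were not, although their median difference turned to -0.27 with totals over every feature. Nuclear-encoded respiratory chain genes were lower in kind 2 by a median log2 difference of -2.89 over 12 members (range -3.29 to -1.59), and ribosomal protein genes by -1.57 over 10 members. The 12 long neuronal genes, among them the synaptic scaffold gene Dlg2, differed by a median of 0.51, and glutamate receptor subunits of the AMPA and NMDA types by -0.04. The median of all 18948 genes was -0.27, and with totals over every feature it was -0.88, with respiratory chain genes at -3.78 and AMPA and NMDA receptor subunits at -0.91. With totals over every feature, which enlarges falls and shrinks rises in kind 2, median CPM of Ppia fell from 2173 in kind 1 to 80.96 in kind 2, that of Ubb from 3771 to 160 and that of Ftl1 from 1187 to 53.5, while ribosomal RNA features rose, Rn18s from 201.3 to 7100 and Rn28s from 50.8 to 1734. In kind 3 brain genes were lower still than in kind 1, with median log2 differences of -7.58 for respiratory chain, -6.07 for ribosomal protein and -4.75 for long neuronal genes, while Pi15, C13H1orf202, Ly96, Sgcz and Ikzf2 had medians of 40145, 70568, 46610, 46737 and 115550 CPM against 0.078, 1.06, 3.91, 5.10 and 18.9 in kind 1. These single genes were chosen after their values were seen. Many kind 3 medians lay near the bottom of the scale, such as Cox8a at 1.11 and Ndufv2 at 0.75 CPM, likewise chosen. The kind 3 differences therefore largely follow levels in kind 1 and do not rank the lists. Only LOC120093067, Zfp532, Nif3l1 and ribosomal RNA features were left out of the totals. Pi15, C13H1orf202, Ly96, Sgcz and Ikzf2 stayed in and diluted the other genes of kind 3. The mean of long neuronal minus respiratory chain genes was higher in 27 of 32 libraries of kind 2 than in all 49 of kind 1, and in 5 it was not. Xist, transcribed from the inactive X chromosome, and Y-linked Ddx3y split the libraries of kinds 1 and 2 but not those of kind 3: 37 libraries of kind 1 were high for Xist and 12 for Ddx3y, 10 and 22 of kind 2, and 0 and 0 of kind 3. In kinds 1 and 2, 0 libraries were high for both and 0 for neither. Differences between these kinds therefore include any between Xist-high and Ddx3y-high libraries. No p-value was computed between kinds.

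**Figure D2:**
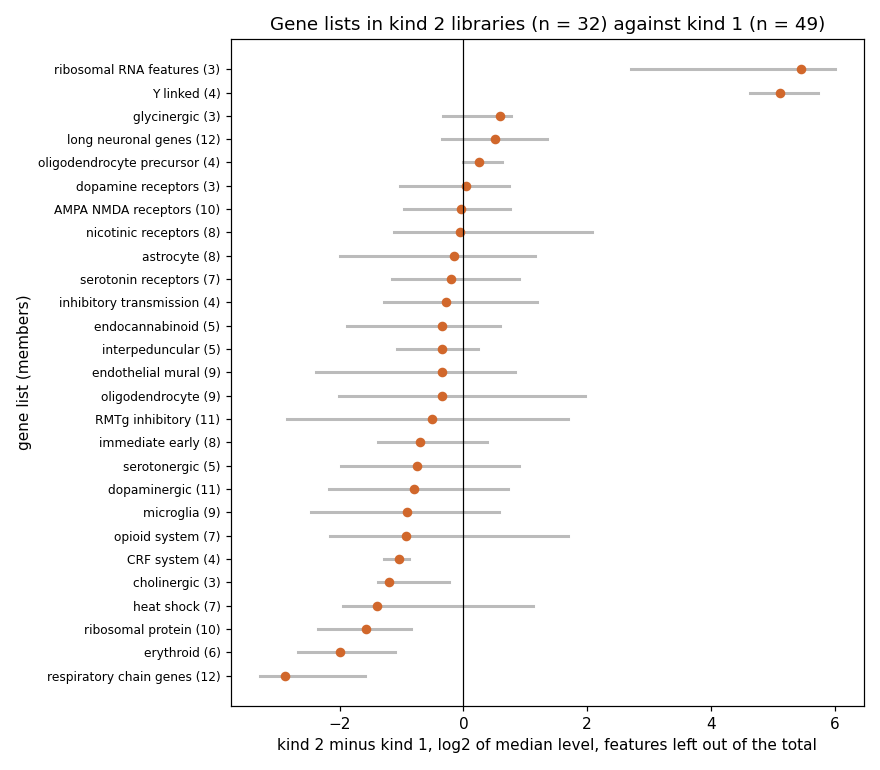
Median difference in log2 level between kind 2 (n = 32) and kind 1 (n = 49) libraries for each gene list (points), with the lowest and highest member as the ends of the grey line. The respiratory chain list lies at -2.89 and the long neuronal list at 0.51 with the dominant features left out of the totals, and at -3.78 and -0.27 with them in.

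Kind 1 libraries carried the markers of an inhibitory tegmental nucleus together with markers of its neighbours. All 11 members of the RMTg inhibitory list passed the filter, among them the transcription factors Gata3 at 55.8 ± 6.26 CPM (SD, n = 49), Sox14 at 44.1 ± 6.23 and Foxp1 at 90.6 ± 11.4, the neuropeptide gene Pnoc at 146 ± 34.7, and Gad1, which makes GABA, at 454 ± 72.1. The mu opioid receptor gene Oprm1 lay at 3.91 ± 1.42 CPM. All 11 dopaminergic members and all 5 serotonergic members passed as well, with Th, the first enzyme of dopamine synthesis, at 248 ± 174 CPM and Tph2, the serotonin enzyme, at 194 ± 58.4. So did 3 of 3 vesicular glutamate transporters, 3 of 3 glycinergic, 5 of 6 interpeduncular and 3 of 5 cholinergic members. Passing the filter is thus not particular to the inhibitory list and does not tell the nucleus from its neighbours. Of the cerebellar list 0 of 5 members and of the noradrenergic list 0 of 4 passed within the 49 libraries; of the forebrain list 2 of 5 passed (Neurod6 and Lamp5), of the ependymal list 2 of 4 and of the choroid plexus list 2 of 5. In the opioid list 7 of 8 members passed, and Oprd1, the exception, averaged 0.064 CPM with 20 of 49 libraries at 0. Values are not adjusted for transcript length, so these levels do not rank genes against each other.

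Dopaminergic, erythroid, immediate early and Y-linked genes varied between rats more than any of 10000 matched random lists of their size. Within the 49 libraries 10 of 10 immediate early, 6 of 6 erythroid and 4 of 4 Y-linked members also differed between series. Of the dopaminergic members 0 of 11 did, adjusted over all genes. The spread of the immediate early, erythroid and Y-linked lists thus includes differences between series, and Ddx3y was high in only 12 libraries. Among the 49 libraries, the median residual SD of 11 lists reached the 97.5th percentile of matched random lists. Dopaminergic, erythroid, immediate early and Y-linked lists were at 100, with median residual SDs of 0.29, 0.74, 1.24 and 1.94 log2 units. These percentiles depend on list size and do not rank the lists: the 3 vesicular glutamate transporters had 0.39. Below 100 were heat shock genes at 99.99, nicotinic receptors at 99.96, vesicular glutamate transporters at 99.88, microglia at 99.49, cholinergic genes at 98.72, the corticotropin-releasing factor system at 98.45 and glycinergic genes at 98.12. The RMTg inhibitory list stood at 73.2, the interpeduncular list at 62.9 and ribosomal protein genes, the lowest, at 7.36. Th ranged from 46.5 to 1067 CPM and the dopamine transporter gene Slc6a3 from 5.52 to 124 CPM, whereas Tal1 ranged from 22.5 to 36.1 CPM. With LOC symbols passed over, the genes of largest residual SD were Xist, Rn18s, Hbbl1, Ndrg3-ps1, Ddx3y, Eif2s3y, Fam111a, Fos, Kdm5d, Fosb, Uty and Junb. Over all 92 libraries only 3 lists (erythroid, immediate early and Y-linked) reached that percentile, and the most variable genes were Pi15, C13H1orf202, Nif3l1, Hpgd, Ly96 and Sgcz, which were high in kind 3.

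Chrna3 and Chrna5, nicotinic receptor genes of the interpeduncular list, varied with the markers of dopamine neurons across rats. Over the 49 libraries the dopaminergic score and the score of 5 markers of the interpeduncular nucleus, a midbrain cell group near the midline, correlated with r = 0.67 (permutation p = 1e-05, the smallest that 100000 permutations can give) and rho = 0.57 (permutation p = 3e-05), with r = 0.61 without the 2 libraries farthest from the median. Within series B to F, r was 0.88, 0.63, 0.38, 0.37 and 0.83. Of the 5 members Chrna3 and Chrna5 rose with the dopaminergic score, and Chrnb4, Pax7 and Irx2 did not pass, with slopes of 0.04, 0.04 and 0.07 log2 units per SD. A score of these 3, picked because they did not pass and so no independent test, had r = 0.27 (permutation p = 0.06) and rho = 0.21 (permutation p = 0.14), and the r of 0.67 is not shown for the list beyond Chrna3 and Chrna5. Of the 6 pairs among the oligodendrocyte, precursor, astrocyte and microglia scores 3 passed; precursor scores missed the threshold with oligodendrocyte (r = 0.36, rho = 0.38, adjusted p = 0.083 for r), microglia (r = 0.22, rho = 0.19, adjusted p = 0.35) and astrocyte scores (r = 0.10, rho = 0.09, adjusted p = 0.71). Astrocyte and microglia scores gave r = 0.58 (permutation p = 2e-05) and rho = 0.59 (permutation p = 2e-05). Oligodendrocyte and endothelial scores gave r = 0.51 (permutation p = 0.00022) and rho = 0.58 (permutation p = 2e-05), and oligodendrocyte precursor and endothelial scores r = 0.47 (permutation p = 0.00065) and rho = 0.44 (permutation p = 0.0016). Oligodendrocyte scores gave r = 0.45 (permutation p = 0.0012) and rho = 0.43 (permutation p = 0.0023) with microglia scores, and r = 0.42 (permutation p = 0.0029) and rho = 0.46 (permutation p = 0.00079) with astrocyte scores. Glycinergic and microglia scores moved in opposite directions, with r = -0.59 (permutation p = 1e-05) and rho = -0.57 (permutation p = 5e-05). Of 91 pairs of 14 lists, 8 passed an adjusted p of 0.05 for Pearson's r, 7 positive and 1 negative. Adjusted p for r ran from 0.00045 for the dopaminergic and interpeduncular pair and for the glycinergic and microglia pair to 0.034 for the oligodendrocyte and astrocyte pair, and without the 2 libraries farthest from the median r was -0.57 for the glycinergic, 0.63 for the astrocyte and 0.45 for the oligodendrocyte scores with the microglia score. Within series B to F, r was -0.42, -0.32, -0.88, -0.74 and -0.31 for the glycinergic and microglia pair and 0.84, 0.51, 0.38, 0.91 and 0.83 for the astrocyte and microglia pair, while the oligodendrocyte and microglia pair (0.64, 0.46, 0.52, -0.01 and 0.56) and the oligodendrocyte precursor and endothelial pair (0.24, 0.42, 0.59, -0.20 and 0.73) fell below 0 in series E. The 8th called pair, erythroid and immediate early, is not given a pooled r because the immediate early scores form separate clusters; within series B to F its r was -0.25, -0.18, -0.84, -0.25 and -0.01.

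Several of these relations changed with the setting. The glycinergic and microglia correlation turned to 0.11 with the first principal component as score and to 0.58 over the 32 libraries of kind 2. With values centred within series, the oligodendrocyte and astrocyte pair (r = 0.35, adjusted p = 0.13) and the oligodendrocyte and endothelial pair (r = 0.39, adjusted p = 0.064) lost the call, and within series C they gave r = 0.04 and 0.11. Without the 2 libraries farthest from the median, the oligodendrocyte precursor and endothelial pair had r = 0.39 (adjusted p = 0.061) and the oligodendrocyte and astrocyte pair r = 0.40 (adjusted p = 0.061). Over all 92 libraries 78 of 78 pairs passed, all positive, and over the 32 libraries of kind 2, 75 of 78, all positive. Totals there include the dominant features, so dilution shared by all lists was not removed. The sign of a pair over kind 2 is therefore no separate test of it.

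**Figure D3:**
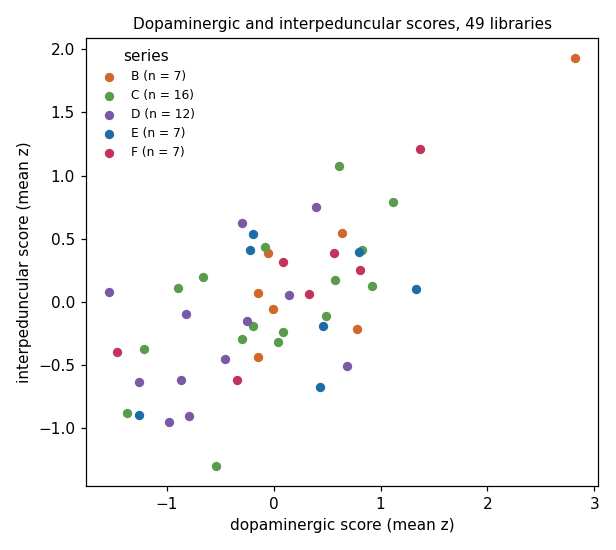
Interpeduncular score against dopaminergic score (both mean z-scored log2 levels) in the 49 libraries of kind 1, with 1 point per library coloured by identifier series. Pearson's r is 0.67 over the 49 libraries and runs from 0.37 to 0.88 within series, with 2 of the 5 interpeduncular members (Chrna3 and Chrna5) following the dopaminergic score.

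Cck, Slc18a2, Nts, Ntsr1 and 4 of 7 nicotinic receptor genes rose with the dopaminergic score. Within the 49 libraries 2167 of 18738 genes outside the list passed, 934 rising and 1233 falling with the score. Cck, a peptide of many dopamine neurons, rose by 0.88 ± 0.05 log2 units per SD (SE), Slc18a2, the vesicular monoamine transporter, by 0.46 ± 0.03, the midbrain factor gene Otx2 by 0.45 ± 0.06, Nts, which encodes neurotensin, by 0.54 ± 0.11 and its receptor gene Ntsr1 by 0.52 ± 0.04. Of 7 nicotinic receptor genes outside the list 4 rose, over all genes and adjusted over the list alone: Chrna5 by 0.59, Chrnb3 by 0.47, Chrna3 by 0.45 and Chrna4 by 0.14. Chrna5 and Chrna3 are also the 2 of 5 interpeduncular members that rose. Wnt2, Ntf3, Tacr3, Slc39a4, Tmem255a, Tmem207 and the opioid peptide gene Pdyn rose as well, by 0.44 to 0.63. Among named genes with 1 sign in all series, the strongest falls were those of Rpl35al2, Osbpl1al, Vof16, Amy1, Mustn1 and Nefm, a neurofilament gene, from -0.32 to -0.30. Foxp1 was the 1 member of 11 in the RMTg inhibitory list that fell (-0.08; 2 fell adjusted over the list alone), Glra1 fell by 0.18, and Grin2b and Grin2d of 10 AMPA and NMDA receptor genes fell by 0.16 and 0.12. Of 100 draws with permuted scores 0 reached the count, and the highest had 5 genes. With Xist and Ddx3y levels as covariates the count was 323, with log10 of the library total 1377.

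Few genes passed with the RMTg inhibitory or the serotonergic score in the main setting. In limma's test, however, 1781 and 3900 genes had an unadjusted p under 0.05. Of the 11 RMTg members only Gata3 (slope 0.12) and Sox14 (0.13) passed with the score that they help to form. Every dopaminergic and serotonergic member passed with its own score. Members help to form their own score, and the unadjusted p that passes differs between scores with the number of genes called. This contrast therefore does not show how far the RMTg members vary together. That was not tested, which limits what the RMTg count can show. For the RMTg score 8 of 18738 genes passed, 7 rising: Vgf, a secreted neuropeptide precursor, by 0.27 ± 0.05 log2 units per SD, Usp2 by 0.17, Eef1a2 by 0.16, the striatal-type phosphodiesterase gene Pde10a by 0.15, the neuronal nuclear protein gene Rbfox3 by 0.15, Galnt17 by 0.14 and the potassium channel gene Kcnc4 by 0.11, while Ets1, an endothelial and immune transcription factor, fell by 0.19 ± 0.03. With series as a covariate Usp2, Eef1a2, Pde10a and Kcnc4 lost the call (adjusted p = 0.059 for each). Of the 10 immediate early members 0 passed over all genes and 8 rose adjusted over the list alone, although the RMTg and immediate early scores, both with higher medians in series E and F, had r of 0.57, -0.25, 0.05, 0.85 and 0.60 within series B to F and 0.21 centred within series (adjusted p = 0.41); 3 of 9 microglia members fell adjusted over the list alone. One of 100 permuted draws gave as many genes, the highest 16. For the serotonergic score 12 of 18744 genes passed, 8 rising and 4 falling, and 5 of them had 1 sign in all series: Arhgap36 rose by 0.27 ± 0.04, Nmur2 by 0.24 ± 0.05 and the serotonin autoreceptor gene Htr1b by 0.21 ± 0.04, and Rem1 and Mical1 fell by 0.21 and 0.16. Without the 5 least correlated libraries Nmur2, Htr1b, Rem1 and Mical1 lost the call (adjusted p from 0.52 to 0.55). Permuted draws gave at most 3 genes. Without the 2 libraries farthest from the median score the counts were 1 and 2. They ranged from 1 to 467 and from 2 to 1648 over all alternatives, so neither count is stable to the setting.

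Ugt8, Cyp51 and part of the endothelial, microglia and astrocyte markers rose with the oligodendrocyte score. Of 18740 genes 2489 rose and 1335 fell with it. Ugt8, which makes the myelin lipid galactosylceramide, rose by 0.28 ± 0.04 log2 units per SD, the sterol synthesis gene Cyp51 by 0.28 ± 0.03, Bace1, the beta-secretase gene, by 0.32 ± 0.06, Map6d1 by 0.39 ± 0.05 and Nipal4 by 0.26 ± 0.03. Naa60, F8a1, Pcyox1, Ip6k1, C19h1orf198, Cog6, Zdhhc9, Bche, Tnfaip6 and Ugt1a7c rose by 0.26 to 0.43. Of the fixed lists, 6 of 9 endothelial and mural members rose, 4 of 9 microglia members (5 adjusted over the list alone), 3 of 8 astrocyte members and 2 of 4 precursor members. With median-of-ratios scaling 4 endothelial, 2 microglia and 2 astrocyte members rose, and with quantile normalization 6, 3 and 1. Of the falling lists, 3 of 10 AMPA and NMDA receptor members and 2 of 7 heat shock members (3 adjusted over the list alone) passed, as did Glra1 (-0.16) and Slc32a1, the vesicular GABA transporter (-0.20). Respiratory chain genes moved against the score in 10 of 12 members (median slope -0.12), as did 3 of 10 ribosomal protein genes (6 adjusted over the list alone); with median-of-ratios scaling 0 of 12 and 0 of 10 passed, with median slopes of -0.08 and -0.03. Tktl2, Hspa1a, Creb3l4, S100a9, Klk5 and Rps29l5 had the most negative slopes among named genes with 1 sign in all series, from -0.43 to -0.30, and S100a9 lost the call with series as a covariate (adjusted p = 0.075). The highest of 100 permuted draws had 1 gene. The count was 1806 with Xist and Ddx3y as covariates, 2336 with median-of-ratios scaling and 6244 with the first principal component as score.

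Over all 92 libraries nearly every gene followed every score. The counts were 18470 for the RMTg inhibitory, 18112 for the dopaminergic, 18328 for the serotonergic, 18549 for the oligodendrocyte and 17591 for the immediate early score, out of 18937 to 18943 genes. Ubb rose by 2.93 log2 units per SD of the RMTg score and 2.70 of the dopaminergic score, Fth1, a ferritin gene, by 3.02 of the serotonergic and 2.89 of the oligodendrocyte score, and Ppia by 2.69 of the immediate early score. Features high in kind 3 fell: Nif3l1 by 4.65 with the RMTg score and C13H1orf202 by 4.79 with the serotonergic score. In all, 17248 genes passed with all 5 scores, and 17248 of these had the same sign with all 5, so the pooled slopes did not separate the scores from each other.

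Immediate early genes, which neurons transcribe within minutes of activity, were higher in identifier series E and F than in B to D. Fos averaged 159 ± 44.9 CPM (SD, n = 7) in series E and 177 ± 63.8 (n = 7) in F, against 10.9 ± 4.64 (n = 7) in B, 9.20 ± 2.86 (n = 16) in C and 7.66 ± 2.73 (n = 12) in D, counting the libraries of kind 1. Fosb averaged 23.1 ± 8.34 and 26.9 ± 11.5 CPM in E and F and 0.41 ± 0.30 in D, and Npas4 15.1 ± 9.01 and 17.6 ± 7.90 against 0.55 ± 0.32. The immediate early score of every library of series E and F (lowest 0.34) was above that of every library of series B to D (highest -0.16). Fos separated likewise, with a lowest value of 37.5 CPM in F against a highest of 20.4 in B. Not every gene did: Arc was as low as 1.39 CPM in E and as high as 2.13 in D. Egr1 was as low as 13.2 CPM in F and as high as 19.4 in B. All 10 members past the filter were higher in E than in D and in F than in D, with log2 differences from D to E of 4.23 ± 0.20 for Fos, 4.02 ± 0.19 for Fosb, 3.58 ± 0.18 for Junb, 3.49 ± 0.19 for Egr1, 3.20 ± 0.19 for Nr4a1, 3.06 ± 0.32 for Npas4 and 1.03 ± 0.19 for Arc (SE). The stress kinase phosphatase gene Dusp1 rose by 1.57, and Nr4a3, Fosl2 and Gadd45g outside the list by 3.25, 2.61 and 2.19.

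**Figure D4:**
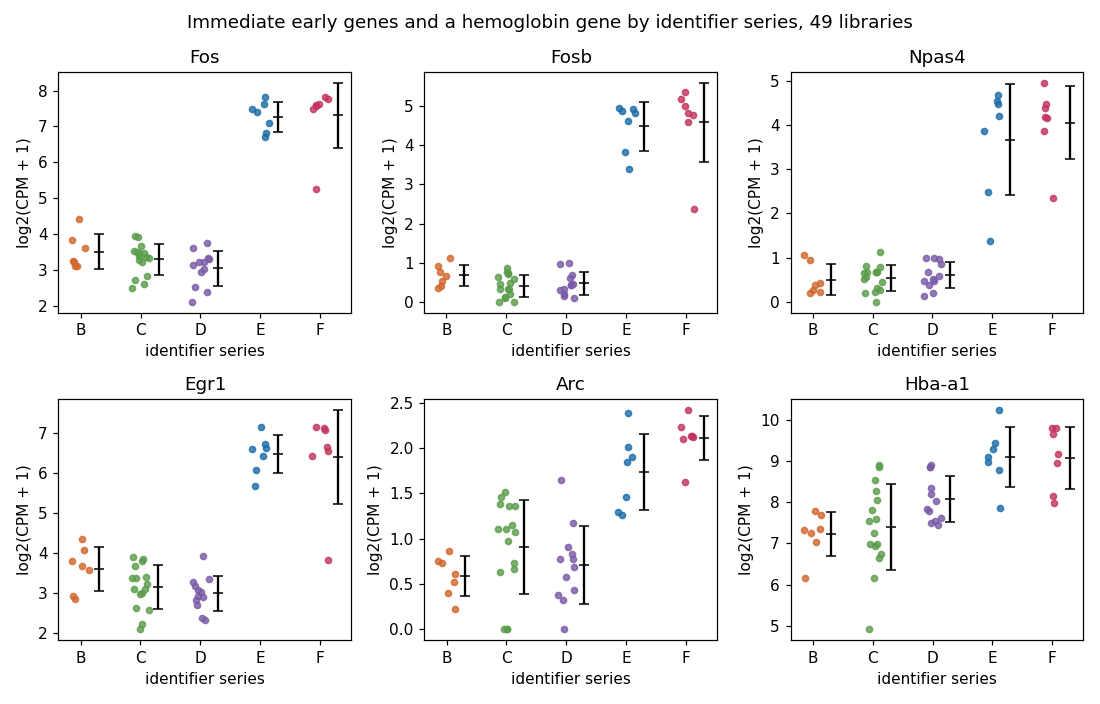
Levels of 5 immediate early genes and of Hba-a1 in the 49 libraries of kind 1 by identifier series, as log2(CPM + 1), with 1 point per library and the mean and SD beside them in black. Fos averaged 159 CPM in series E and 177 CPM in F against 7.66 CPM in D.

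Blood and Y-linked transcripts also differed between series. Of the fixed lists, 10 of 10 immediate early, 6 of 6 erythroid and 4 of 4 Y-linked members and Xist passed the F test over series B to F within the 49 libraries. Hba-a1, an alpha globin gene, averaged 289 ± 118 CPM in D, 605 ± 303 in E and 598 ± 272 in F; 2 of 6 erythroid members were higher in E than in D and 1 of 6 in F than in D, 5 and 6 of them adjusted over the list alone. Of 7 heat shock members only Dnajb1 was higher, by 0.66 ± 0.16 in E and 0.85 ± 0.18 in F. Libraries high for Ddx3y numbered 2 in B, 10 in C and 0 in D to F of kind 1. Pnoc was the 1 of 11 RMTg inhibitory and 1 of 7 opioid members that passed the F test, and Esam, an endothelial adhesion gene, the 1 of 9 endothelial and mural members (4 adjusted over the list alone). No dopaminergic, serotonergic, astrocyte, microglia, oligodendrocyte or AMPA and NMDA receptor member passed over all genes, and 1 of 9 oligodendrocyte members passed adjusted over the list alone. Between pairs of series, dopaminergic members differed by a median of 0.43 log2 units from D to E and 0.38 from D to F. Of the 11 members 0 passed over all genes, and 1 was higher in E and 4 in F adjusted over the list alone. Median dopaminergic scores were -0.62 in D, 0.44 in E and 0.33 in F.

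Across series B to F, 320 of 18749 genes differed within the 49 libraries. With LOC symbols passed over, the 10 of smallest p were Fosb, Fos, Nr4a1, Junb, Nr4a3, Npas4, Btg2, Fosl2, Gadd45g and Egr1. Series D and E differed in 373 genes, 120 higher and 253 lower in E, and D and F in 285, 120 higher and 165 lower in F. Among those lower, the motor protein gene Kif5a fell by 1.005 in E and 0.92 in F, Pnma8c by 1.004 and 1.01, and Diaph2 by 0.84 and 0.85. Kif5a, Pnma8c and Diaph2 were chosen after their values were seen. Between E and F limma called 0 genes, with 499 at an unadjusted p under 0.05. Over all 92 libraries and 6 series 14000 of 18948 genes differed, in libraries whose kinds are unequally spread over the series. The count within the 49 libraries was 113 with a Kruskal-Wallis test and 105 with Xist and Ddx3y as covariates.

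Egr4, Gadd45g, Gpr3 and Srxn1 rose with the immediate early score within the 49 libraries and had the largest slopes among named genes with 1 sign in all series. Of 18739 genes 1028 rose and 1632 fell. Egr4 rose by 1.32 ± 0.05 log2 units per SD, Gadd45g by 1.06 ± 0.04, Gpr3 by 0.84 ± 0.05, Srxn1 by 0.82 ± 0.04, Rrad by 0.53, the polo-like kinase gene Plk2 by 0.51, C3h11orf96 by 0.44, Atf3 by 0.33 and Map3k6 by 0.32. With series as a covariate, slopes were 0.50 for Egr4, 0.31 for Gadd45g, 0.21 for Gpr3 and 0.23 for Srxn1. Those slopes are per SD of the score centred within series, another unit, so their sizes cannot be set against the slopes above. These 9 genes passed with series as a covariate too. Per1, Ppp1r15a, Rgs2, Trib1 and Zfand2a, and the falling genes Hrct1, Apbb1ip, Prox1, Scgb1c1, Dock8 and Sox9, did not, with adjusted p from 0.057 to 0.84. All 6 erythroid members rose over the 49 libraries, by a median of 0.50, but within series B to F the erythroid and immediate early scores had r of -0.25, -0.18, -0.84, -0.25 and -0.01. The count was 76 with series as a covariate and 1329 without the 2 libraries farthest from the median score.

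Xist, the Y-linked genes and a set of autosomal genes fell into 2 separated levels. Within the 49 libraries 38 genes did so, 28 on autosomes, 5 on X and 5 on Y, against a median of 2 and at most 6 in normal draws. With LOC symbols passed over, the gap was widest for Xist, at 6.46 log2 units with 12 libraries low and 37 high, followed by Eif2s3y at 4.99, Ddx3y at 4.18, Kdm5d at 3.49 and Uty at 3.29, each with 12 libraries high. All 12 libraries high for Ddx3y were low for Xist. Among autosomal genes Defb17, a beta-defensin gene on chromosome 9 (position 28380421), had a gap of 2.48 with 13 libraries high, Fam111a on chromosome 1 (219065542) 2.31 with 20 high, Spetex2el1 on chromosome 9 (2900533) 2.25 with 13 high, and Ndrg3-ps1, a pseudogene on chromosome 3 (165925107), 2.14 with 37 high. The high libraries of Defb17 and Fam111a came from all 5 series. Rn18s, with a gap of 2.16, is a ribosomal RNA feature whose values equal those of another feature, LOC120102105. Of the 38 genes, 6 were activity genes (Fos, Fosb, Egr1, Egr4, Npas4 and Nr4a1) whose high libraries all came from series E and F. Over all 92 libraries 7349 genes had such a gap, 18 of them among the 38, and the widest were those of Pkd2l2, Col8a1 and Tmem74, with 11 libraries high.

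**Figure D5:**
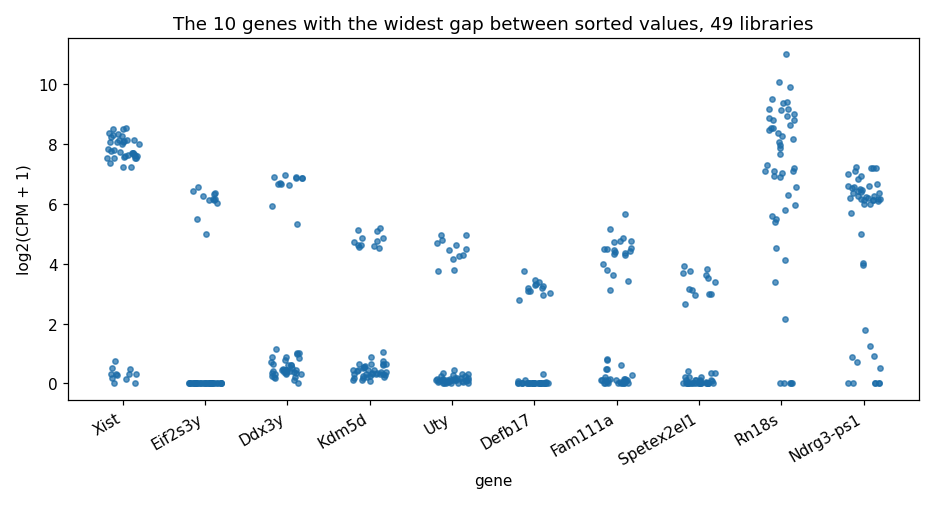
Levels of the 10 genes with the widest gaps, LOC symbols passed over, in the 49 libraries of kind 1, as log2(CPM + 1), with 1 point per library. Xist has 12 libraries low and 37 high, and the 4 Y-linked genes have 12 high.

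Neighbouring genes were only slightly more alike than genes placed at random. The median r of adjacent genes was 0.021 over 18727 pairs in the 49 libraries, against 0.0042 after shuffling gene order and at most 0.0093 (permutation p = 0.001, the smallest that 1000 shuffles can give). Over all 92 libraries it was 0.013 over 18926 pairs, against a shuffled highest of 0.0035 (permutation p = 0.001). Genes are not independent replicates in this test. With LOC symbols passed over, the pairs of highest r were Cers1 and Gdf1 on chromosome 16 (r = 1), which are listed at the same position, 3 Y-linked pairs (Eif2s3y and Uty at 0.98, Uty and Ddx3y at 0.95, Kdm5d and Eif2s3y at 0.95), the class I histocompatibility genes RT1-CE15 and RT1-CE14 on chromosome 20 (0.96), and the alpha globin genes Hba-a2 and Hba-a1 on chromosome 10 (0.95). For Cers1 and Gdf1 and for the paralogous pairs, reads shared between members were not ruled out. Without removing principal components the median was 0.098 against 0.026 after shuffling.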

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

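The restriction to 49 libraries, every alternative within them and the comparisons of pairs of series were chosen after seeing the data; alternatives over all 92 libraries were otherwise planned. No paired analysis was possible because the samples form 1 group with 1 library per animal. Where no cause is named below, the cause was not tested. Over all 92 libraries the counts of genes that followed the 5 scores stayed within 1.5 times of the values reported under every alternative chosen before the data were examined. Restricting to the 49 libraries, which leaves fewer libraries of 1 kind, gave 8 genes for the RMTg inhibitory, 2167 for the dopaminergic, 12 for the serotonergic, 3824 for the oligodendrocyte and 2660 for the immediate early score, 320 genes between series, 38 genes with 2 levels, 11 variable lists and 8 correlated pairs of lists. Without the low-value filter, which lets more lists reach 3 members, 168 pairs of lists were called, and with the stricter filter 45. Genes with 2 levels numbered 17173 with a pseudocount of 0.1 and 4821 with quantile normalization, which also gave 8532 genes between series. Without the 5 least correlated libraries, 5 lists were variable.

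Within the 49 libraries the RMTg inhibitory count was 38 with the first principal component as score, 29 with the oligodendrocyte score as a covariate, 4 without the filter, 467 with quantile normalization, 49 with median-of-ratios scaling, 59 without the 5 least correlated libraries and 1 without the 2 libraries farthest from the median score. The serotonergic count was 23 with series, 240 with the oligodendrocyte score and 453 with log10 of the total as a covariate, 128 with limma-voom weights, 2 with Spearman's correlation, 2 without the 2 farthest libraries, 7 without the filter, 40 with quantile normalization, 1648 with median-of-ratios scaling and 4 without the 5 least correlated libraries. The dopaminergic count was 1392 with limma-voom weights, 1377 with log10 of the total and 323 with Xist and Ddx3y as covariates. The oligodendrocyte count was 6244 with the first principal component, 1806 with Xist and Ddx3y and 2336 with median-of-ratios scaling. The immediate early count was 76 with series, 1377 with the oligodendrocyte score, 1555 with log10 of the total and 221 with Xist and Ddx3y as covariates, 1329 without the 2 farthest libraries, 4111 with Spearman's correlation and 1418 without the filter.

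Between series the count was 113 with the Kruskal-Wallis test, 105 with Xist and Ddx3y as covariates and 542 without the 5 least correlated libraries. Series D and E differed in 120 genes without the filter; D and F in 177 without it and in 438 without the 5 least correlated libraries. Genes with 2 levels numbered 23 at a gap of 1.5 log2 units, by construction fewer, 15 with the stricter filter, which tests fewer genes, and 104 with a pseudocount of 0.1. With the stricter filter 7 lists were variable. The correlated pairs of lists numbered 6 to 11, and the neighbour correlation kept its sign and call in both sets.

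For the 84 named slopes and correlations, 979 of 1054 alternative values kept sign and call, 72 lost the call and 3 reversed: the glycinergic and microglia correlation was 0.11 with the first principal component and 0.58 over the 32 libraries of kind 2, and the erythroid and immediate early correlation was -0.20 with series as a covariate. Totals over kind 2 include the dominant features, so signs there are no separate test. Xist and Ddx3y as covariates, rank tests of slopes and limma-voom weights were applied to gene counts only. The named genes were thus not checked against Xist and Ddx3y levels, which lowered the dopaminergic, oligodendrocyte and immediate early counts. With median-of-ratios scaling 0 of 12 respiratory chain and 0 of 10 ribosomal protein genes passed with the oligodendrocyte score. Depth limits kinds 2 and 3 most, where totals reach down to 1.72 M.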

Other observations

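The tests of depth and of dilution for the kinds of library, and the test of Y-linked transcripts for the immediate early genes, were chosen after the result was seen, as were all comparisons within the 49 libraries.

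Nicotinic receptor genes reached the 97.5th percentile of matched lists in their variation between rats. Serotonin, dopamine, AMPA and NMDA receptor genes and endocannabinoid genes did not reach it. Within the 49 libraries the nociceptin receptor gene Oprl1 lay at 31.6 ± 4.57 CPM (SD, n = 49), Htr2c at 253 ± 53.7, Htr1a at 26.1 ± 4.31, Cnr1, the cannabinoid receptor gene, at 28.97 ± 5.88, and Napepld, an endocannabinoid enzyme gene, at 21.7 ± 2.64. Percentiles of residual SD were 99.96 for nicotinic receptors, 96.45 for the opioid system, 80.35 for serotonin receptors, 73.95 for dopamine receptors, 33.28 for AMPA and NMDA receptors and 33.11 for the endocannabinoid list. The corticotropin-releasing factor receptor gene Crhr2 ranged from 0.11 to 7.27 CPM and Chrna5 from 0.90 to 40.1 CPM. Hspa1b, a heat shock gene, ranged from 1.23 to 190 CPM with a median of 7.42.

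Libraries of kinds 2 and 3 gave large shares of their counts to a few features and differed from kind 1 in other genes too. The features did not simply dilute all other genes alike in kind 2, since with them left out long neuronal genes and respiratory chain genes still differed by 3.40 log2 units. Depth stays open for kind 2: over totals of 9.55 to 13.7 M, long neuronal minus respiratory chain genes differed by a median of -2.15 log2 units between 3 libraries of kind 2 and 14 of kind 1, opposite in sign to the median over kind 2, and 3 libraries are too few to decide. Within kind 2 that difference between lists fell with log10 of the total (r = -0.68, permutation p = 1e-05, the smallest that 100000 permutations can give; rho = -0.58, permutation p = 0.00067; r = -0.60 without the 2 libraries of most extreme total; r = -0.67 in series B, n = 18, and r = -0.84 in series C, n = 8). Reads from genomic DNA were tested with 254 olfactory and vomeronasal receptor genes, whose share of counts was 3.81 times that of kind 1 in kind 2, with overlapping ranges (0.0033% to 0.045% against 0.0033% to 0.0071%), and 0.15 times in kind 3, a log2 difference of -2.73 against -4.75 for long neuronal genes. The 10 largest features take 77.1% to 86.4% of counts in kind 3 and dilute every other share, so the limit of 2 set beforehand was wrong there, and genomic DNA cannot be told apart from other sources for either kind. Degraded RNA was not tested, nor was any biological explanation, since the labels give 1 group.

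Immediate early genes were higher in series E and F than in series B to D. Blood left in the tissue is argued against, since the difference in score between E and D was 1.99 ± 0.13 (SE) and stayed at 2.05 ± 0.14 with the erythroid score as a covariate, although erythroid genes were higher in E and F as well. Library depth is argued against in the same way, with a difference of 1.91 ± 0.13 given log10 of the total. Nor can libraries with Y-linked transcripts account for it, since series D, E and F hold none in kind 1 and the lowest score in E and F was 0.71 above the highest in D. What stays open is anything else that differed between series, such as handling before the tissue was taken or a batch of collection, which the labels do not give; no biological explanation was tested.

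For the series differences over all 92 libraries (14000 genes) 1 of 100 splits, the real one, gave as many, and the highest other gave 47. Within the 49 libraries (320 genes) it was again 1 of 100, and the highest other gave 3. Chance is thus unlikely for both, but 100 splits cannot exclude it, and the 49 libraries were chosen after seeing the data. For D against F (285 genes) 1 of 100 splits, the real one, gave as many, and the highest other gave 142. That is the lowest rank that 100 splits can give, for a pair chosen after seeing the data, so it alone cannot exclude chance. For D against E (373 genes) 2 of 100 splits, the real one included, gave as many, but the other gave 1063 genes, and what that split follows was not tested. For E against F limma called 0 genes, so the splits decide nothing: all 100 of 100 gave as many, and the highest other gave 3.

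Nearly all genes followed each of the 5 scores over all 92 libraries, in 92.9% to 97.9% of genes tested. With values centred within the 3 kinds the share was 78.4% for the RMTg inhibitory, 60.3% for the dopaminergic, 63.03% for the serotonergic, 62.5% for the oligodendrocyte and 14.9% for the immediate early score, and within kind 1 alone it was 0.043%, 11.6%, 0.064%, 20.4% and 14.2%. The kind of library cannot be told apart from other sources of the pooled relation, because libraries of kinds 2 and 3 also vary within their kind. Permuted scores over all 92 libraries gave a median of 0 genes but up to 16755 in single draws. No biological explanation was tested.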
